A study of Caenorhabditis elegans with 4 samples.

How the data were processed

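The series holds 4 samples of Caenorhabditis elegans hermaphrodites at the L2 larval stage, 2 chromatin immunoprecipitation (ChIP) samples and 2 input samples, numbered replicate 1 and replicate 2 in their titles. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde, sonicated and precipitated with anti-GFP antibody, and part of the sonicated supernatant was kept as input. The strain carries a transgene that expresses the nuclear hormone receptor family protein NHR-237 fused to GFP. The labels do not say whether the replicates came from separate cultures.

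The files used are 3 lists of binding regions, 1 for each ChIP sample and 1 combined list for the series. Per the file headers, positions are on the WormBase WS220 genome build. The source column of each file reads spp_via_IDR, which names the SPP peak caller and the irreproducible discovery rate. The aligner, the program versions, the thresholds, the use made of the input and the way in which the replicates were combined are not given in the sources used here. Each region in the deposited lists has 1 score, read here as the −log10 of a q value (false discovery rate) given by the authors' peak caller. No header states this unit. It was inferred because the highest score, shared by 271 regions in the replicate 1 list and 236 in the replicate 2 list, equals −log10(1/(2k − 1)) with k the number of tied regions (2.73 and 2.67). In the combined list the relation gives 244 tied regions against 230 found, so the unit is less certain there. Each region also has an order number in its name. This number was read as the authors' order of strength, since it followed the score across regions (Spearman's rho of −0.998 in replicate 1, −1.00 in replicate 2 and −0.793 in the combined list, where 230 regions share the highest score). Among regions tied at the highest score of a list, the score cannot test this reading. Scores and order numbers are the authors' own and were used to order and filter regions within a list. They were also correlated between the 2 replicate lists to measure their agreement. The read depth is unknown, since the lists hold no read counts, and no signal of the input samples was analysed here.

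Sharing between lists was counted as regions with at least 1 bp of overlap. It was compared with 10000 random placements of the regions on their own chromosome with their widths kept, as a one-sided permutation test whose smallest possible p is 0.0001. For the combined list against the replicate lists only the shares are reported, since both rest on the same ChIP samples and overlap above random placement follows from that. The agreement of scores was measured over mutually best-ranked shared regions, with 100000 permutations (smallest possible p 1e-05, two-sided). The score is already on a log scale and was not transformed again. The length of each WS220 chromosome was approximated by the largest region end on it in any of the lists, here called its span. Counts per chromosome were compared with the share of the nuclear span by two-sided exact binomial tests with Benjamini-Hochberg adjustment over the 6 chromosomes. Positions within chromosomes were compared with the middle 50% of the span in the same way. Alternatives to the share of X were judged on unadjusted p values. Intervals of shares are 95% Wilson intervals. They cover counting error only. The intervals and the binomial tests treat regions as independent, which neighbouring or overlapping regions are not. None of the tests measures the spread between replicate samples.

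The main tests, 23 of the 53 alternatives and the rule for named items were fixed before the data were examined. The rule names the 10 strongest combined regions by position when no annotation of the same build is at hand. The gene table in hand belongs to the WBcel235 build, so regions were not assigned to genes. The planned tests of distance to transcription start sites, of gene lists and of motifs, the look at the nhr-237 and unc-119 loci and the comparison with the share of genes on X were therefore not run. The comparison of the 25 strongest regions with the rest and the separate tests of chromosomes other than X, with all their alternatives, were chosen after the lists had been seen. The alternatives fixed beforehand were other overlap rules, the better-ranked 50% of a list, replicate lists as long as the combined list, each replicate alone for the tests of X and of chromosome centres, a narrower middle part of the chromosomes and the autosomes alone. Those added after the lists had been seen include the limit of a q value of 0.05, nuclear chromosomes only, merged regions, placement within 20 kb of the own position, order numbers in place of scores and lists limited to, or without, the strongest regions.

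Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9. The sharing test was tested on simulated lists of 8344 regions against a list as long as that of replicate 2. With 0, 20 and 50% of regions shared beyond chance, it returned 18.9, 35.3 and 59.4% shared, where 19.3, 35.4 and 59.6% were expected. For the X test, 200 simulated lists of 322 regions gave a p below 0.05 in 4.50% of lists when the X share equalled that of the span, and in 99.5% when it was 30%. Simulated regions were drawn independently of each other within a list. The overlapping and grouped regions of the real lists were not simulated, so these rates need not hold for them.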

Results

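Binding of the GFP-tagged nuclear hormone receptor family protein NHR-237 was mapped by ChIP sequencing in whole L2 larvae, an early stage of post-embryonic growth. The data are 2 replicate lists of regions and 1 combined list. The replicate 1 list held 8344 regions, of which 8323 lay on the nuclear chromosomes, and the replicate 2 list held 21504, of which 21482 were nuclear. The combined list held 322 regions, all nuclear. Most regions had 1 fixed width within a list: 490 bp for 8319 regions of replicate 1, 504 bp for 21469 regions of replicate 2 and 536 bp for 278 combined regions. The combined regions covered 158 kb, or 0.158% of the nuclear span. Both replicate lists were dominated by weak regions. The median score corresponded to a q value of 0.886 in replicate 1 and 0.841 in replicate 2. At a q value of 0.05 or less there were 430 regions in replicate 1 and 561 in replicate 2. With the score read in the same way, each combined region had a q value of 0.0253 or less, and 230 of the 322 shared the lowest value of 0.00205.

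The first question was where the strongest regions lay. Among the 10 strongest combined regions, 9 lay on the X chromosome and 1 on chromosome III. The strongest was at X 11093905 to 11094335 (WS220), and was placed first in the replicate 1 list and at place 2 in the replicate 2 list. The next regions were X 9465606 to 9465995 (places 4 and 3 in replicates 1 and 2), X 13700597 to 13700989 (places 3 and 4) and X 6296317 to 6296792 (places 2 and 5). These were followed by X 4209049 to 4209435 (places 7 and 9), X 16056320 to 16056703 (places 6 and 10) and X 2996853 to 2997339 (places 8 and 13). The eighth and ninth were X 14525599 to 14526070 (places 5 and 18) and X 11937329 to 11937628 (place 14 in both replicates). The region on chromosome III, at 3867395 to 3867718, held place 10 in the combined list and places 12 and 11 in the replicates. These 10 regions were 300 to 487 bp wide, and each had a partner within the first 18 places of both replicate lists. The combined list rests on the same ChIP samples, so these places give no separate support. All 10 shared the highest score of the combined list, so that their order rests on the authors' order number. Genes at these positions were not assigned here.

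**Figure D1:**
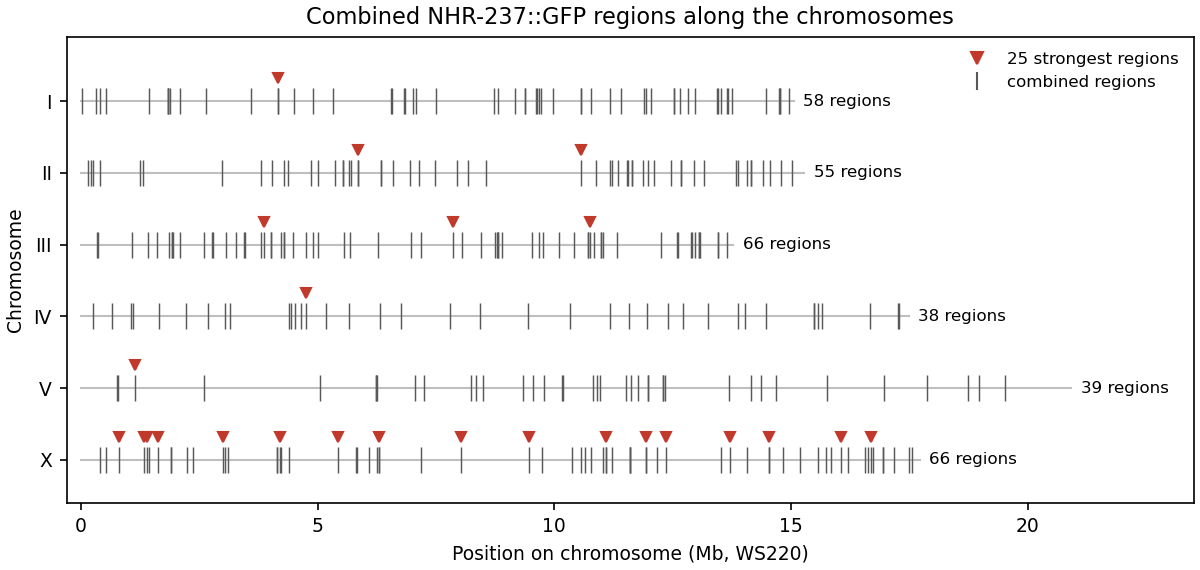
Positions of the 322 combined regions (vertical ticks) along the spans of the 6 nuclear chromosomes in Mb, with the 25 strongest marked by red triangles. Of the 25 strongest regions, 17 lie on X, spread from position 806501 to 16682219, and the other 8 are scattered over the 5 autosomes.

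The excess of X was held by the strongest regions. Of the 25 strongest combined regions, 17 were on X (68.0%, 95% Wilson interval 48.4 to 82.8%), 3.85 times the X share of the nuclear span (17.7%). Of the remaining 297 regions, 49 were on X (16.5%, 12.7 to 21.1%). The difference between the 25 strongest and the rest had an odds ratio of 10.8 (Fisher's exact test, two-sided, p = 9.16e-08). Because the limit of 25 was set after the list had been seen, the order was also permuted 10000 times while the limit was left free from place 10 onwards. An X excess as large at any limit gave p = 0.0001, the smallest these permutations can give. The other 8 regions among the 25 strongest were on chromosomes I (1 region), II (2), III (3), IV (1) and V (1). After those on X and the named region on III, the best placed autosomal regions, chosen after their values were seen, were II 5844683 to 5844905 at place 16, IV 4749920 to 4750217 at place 17 and III 10758982 to 10759281 at place 18.

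The same pattern was present in each replicate list taken alone. In replicate 1, 17 of the 25 strongest nuclear regions were on X, and in replicate 2 15 of 25 were (60.0%, 40.7 to 76.6%). At places 26 to 50, X held 20.0% of regions in the combined list, 20.0% in replicate 1 and 16.0% in replicate 2. At places 201 to 322 it held 18.0, 20.5 and 16.4%. Of the 17 strongest X regions of the combined list, 16 had their partner among the 25 strongest nuclear regions of replicate 1 and 15 among those of replicate 2. The combined list rests on the same ChIP samples, so this match gives no separate support. The 17 regions were 188 to 487 bp wide. The 230 regions that shared the highest score held 20.4% X regions, so the score alone does not separate the strong X regions from the others. The comparison depends on the order number, in the replicate lists as well. There 271 regions of replicate 1 and 236 of replicate 2 share the highest score, the 25 strongest among them. None of the 4 samples came from worms without the tagged protein.

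**Figure D2:**
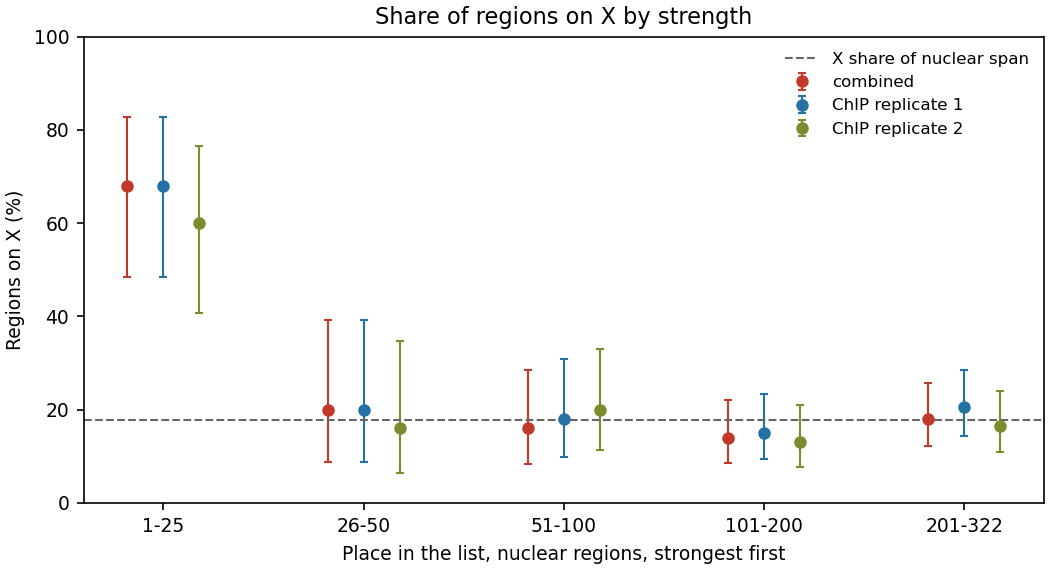
Percent of nuclear regions on X by place in the combined list and in each replicate list, strongest first. Points are shares, bars are 95% Wilson intervals, and the dashed line is the X share of the nuclear span (17.7%); only places 1 to 25 lie above the line with their whole interval, at 68.0, 68.0 and 60.0%.

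Across the whole combined list, chromosome III held the most regions per Mb and chromosome V the fewest. Chromosome III held 66 of 322 regions (20.5%), or 4.79 regions per Mb, 1.49 times its share of the span (interval 1.20 to 1.84, exact binomial test, adjusted p = 0.00256). Chromosome V, the longest, held 39 regions (12.1%), or 1.86 per Mb, 0.580 times its share (0.431 to 0.773, exact binomial test, adjusted p = 0.000293). Chromosome IV held 38 regions, 0.676 times its share (0.50 to 0.905, exact binomial test, adjusted p = 0.0130). X held 66 regions (20.5%), 1.16 times its share, which did not pass the test (0.931 to 1.43, exact binomial test, unadjusted p = 0.188, adjusted p = 0.226). Chromosomes I with 58 regions and II with 55 did not pass the exact binomial test either (adjusted p = 0.207 and 0.352). In the full replicate lists, most of whose regions are weak, chromosome III was also above its share (1.21 times in replicate 1 and 1.15 times in replicate 2, exact binomial test, adjusted p = 2.11e-13 and 2.58e-16) and chromosome V below it (0.840 and 0.917 times, adjusted p = 1.31e-13 and 7.30e-10). The direction of both departures was thus shared by mostly weak calls and was not particular to the combined regions. Why the chromosomes differ was not tested. These p values count overlapping regions as separate. Merging leaves 7725 of the 8323 nuclear regions of replicate 1 and 18462 of the 21482 of replicate 2. The full lists were not tested after merging. Chromosome IV did not pass the exact binomial test in either full list (0.982 and 0.970 times, adjusted p = 0.554 and 0.0619), and chromosome I passed it in replicate 2 (1.05 times, adjusted p = 0.00464) but not in replicate 1 (1.04 times, adjusted p = 0.307). At a q value of 0.05 or less the replicates differed in which chromosomes passed the exact binomial test. Chromosome V was below its share in both (0.680 times in replicate 1 and 0.627 times in replicate 2, exact binomial test, adjusted p = 0.00339 and 1.85e-05). Chromosome III was above its share in replicate 1 (1.31 times, exact binomial test, adjusted p = 0.0304) and did not pass in replicate 2 (1.18 times, adjusted p = 0.210). X was above its share in replicate 1, with 93 of 416 regions (1.26 times, exact binomial test, adjusted p = 0.0304), and did not pass in replicate 2 (1.07 times, adjusted p = 0.512). Chromosome I was the densest in replicate 2, at 6.97 regions per Mb against 6.39 on chromosome III (1.29 times its share, exact binomial test, adjusted p = 0.0203), and did not pass in replicate 1 (1.10 times, adjusted p = 0.447). Chromosome IV passed in neither (0.785 and 0.929 times, exact binomial test, adjusted p = 0.0676 and 0.512). The differences between replicates were not themselves tested.

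With the 322 strongest nuclear regions of replicate 2 in place of the combined list, chromosome III at 18.0% and chromosome IV at 16.1% did not pass the exact binomial test (adjusted p = 0.0868 and 0.729), while chromosome V at 12.4% did (adjusted p = 0.000679). Chromosome III lay close to the threshold, since among the 304 nuclear regions within the first 322 places of replicate 2 it held 18.75% and passed (exact binomial test, adjusted p = 0.0461).

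No concentration of regions in the chromosome centres was detected, a comparison made because centres and arms of worm autosomes differ in gene density. Of the 322 combined regions, 154 (47.8%, interval 42.4 to 53.3%) were centred in the middle 50% of their chromosome (exact binomial test, two-sided, p = 0.469). On the autosomes 128 of 256 regions were (50.0%). Chromosome V had 28 of its 39 regions in the middle 50% (71.8%, 56.2 to 83.5%), and X had 26 of 66 (39.4%, 28.5 to 51.5%). Neither passed the exact binomial test after adjustment over the 6 chromosomes (adjusted p = 0.0569 and 0.327).

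The replicates were compared to see how far binding regions were found again. Of the 8344 regions of replicate 1, 3334 (40.0%) overlapped a region of replicate 2, against 19.2% ± 0.432 (SD over 10000 random placements). The permutation p was 0.0001, the smallest possible. In the better-ranked 50% of each list 32.8% of regions were shared, against 10.3% at random. Of the 322 strongest regions of each list, 177 of replicate 1 (55.0%) overlapped those of replicate 2, against 4.63% at random. With a q value of 0.05 or less in both lists, 230 of the 430 regions of replicate 1 (53.5%) were shared, against 3.77% at random. Both this set and the 322 strongest include MtDNA regions, 14 of the 430 in replicate 1. Placed at random these stayed on MtDNA, 95.5% of whose span lay under the full replicate 2 list. Chance for nuclear regions alone is therefore lower than 4.63 and 3.77%, and was not computed. For the combined regions, all nuclear, it was 0.314% against the 322 strongest regions of replicate 2. Against its regions at a q value of 0.05 or less it was 0.556%. All these shares between the replicates are of replicate 1 regions, the shorter list. Seen from replicate 2 the share of strong regions was lower. Of its 543 nuclear regions at a q value of 0.05 or less, 214 (39.4%) overlapped such a region of replicate 1. The other way it was 216 of 416 (51.9%). The share of the full replicate 2 list was not computed. Random placement takes no account of the clustering of binding sites at promoters or open chromatin. With each region placed within 20 kb of its own position, 21.1% were shared by chance.

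**Figure D3:**
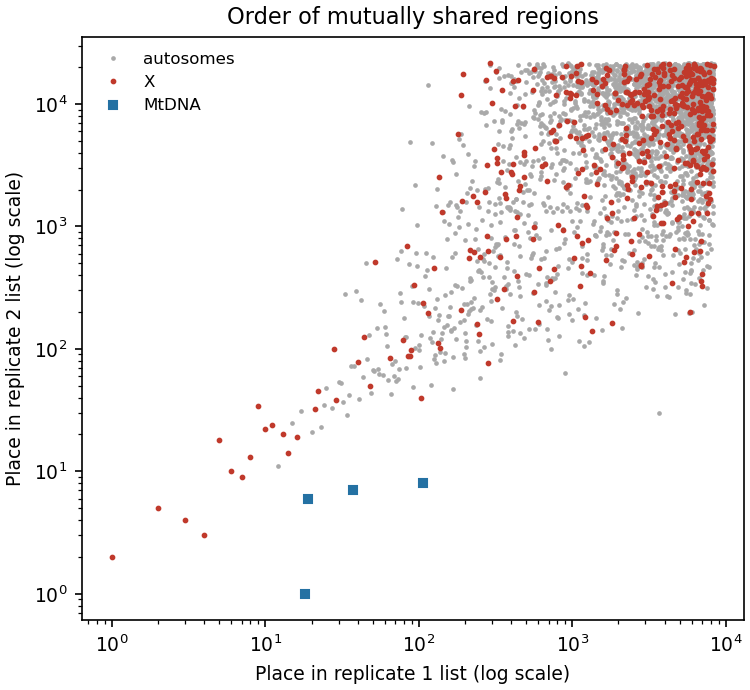
Place of each of 3037 mutually shared regions in the replicate 1 list (x axis) and the replicate 2 list (y axis), both on log scales, where place 1 is the strongest. Grey points are on autosomes, red points on X and blue squares on MtDNA; the points in the lower left corner, where both lists place their strongest nuclear regions, are mostly on X.

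Scores of shared regions rose together in the replicates. Over 3037 mutually best-ranked pairs, Spearman's rho was 0.354 and Pearson's r 0.650, both with a permutation p of 1e-05, the smallest possible. This correlation is across regions, which are not independent replicates. Within the 309 pairs that overlap a combined region, rho of the scores was 0.0509 (permutation p = 0.375). Many of these scores tie at the highest value, but untied pairs were not tested apart, so the cause of the low value stays open. The order numbers of the same 309 pairs had a rho of 0.439 (permutation p = 1e-05).

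The combined regions were found again in the replicate lists almost without exception. All 322 overlapped a region of replicate 1, against 7.95% ± 1.52 (SD) at random, and 320 (99.4%) overlapped a region of replicate 2, against 19.4% ± 2.18. The combined list rests on the same ChIP samples as the replicate lists, so overlap above random placement follows from its making, and no p is given. The regions without a partner in replicate 2 were III 2597009 to 2597544 and IV 7791144 to 7791679, at places 235 and 318. Centres of combined regions lay a median of 20.0 bp from the partner in replicate 1 and 26.5 bp from that in replicate 2. The partner had a q value of 0.05 or less for 286 combined regions in replicate 1 and for 241 in replicate 2. The weakest partner stood at place 3671 of replicate 1 and place 14183 of replicate 2.

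Many strong regions of a single replicate were outside the combined list. Of the 416 nuclear regions of replicate 1 at a q value of 0.05 or less, 288 (69.2%) overlapped a combined region, and 46 overlapped no region of replicate 2 at any score. Of the 543 such regions of replicate 2, 242 (44.6%) overlapped a combined region and 184 overlapped no region of replicate 1. The strong regions outside the combined list were on X for 31 of 128 in replicate 1 (24.2%, interval 17.6 to 32.3%) and for 52 of 301 in replicate 2 (17.3%, 13.4 to 21.95%). Both intervals include the X share of the span (17.7%). No test of the difference between replicates was made, since each is 1 sample.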

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

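The tests in this part, apart from the question of untagged controls, were chosen after the lists had been seen.

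Regions on the mitochondrial chromosome (MtDNA) were flagged because they appear in both replicate lists and enter no comparison of the combined list, which holds none. The replicate 1 list had 21 MtDNA regions and the replicate 2 list 22, or 1.60 and 1.67 per kb, against 0.0830 and 0.214 per kb on the nuclear chromosomes. In replicate 2 the 22 regions fell into 4 distinct intervals of up to 3894 bp. Its density of 1.67 per kb therefore counts repeated intervals and does not show that many separate regions. The first place of the whole list was held by 1 of these intervals. Together the regions covered 95.5% of the MtDNA span in replicate 2 and 63.7% in replicate 1. Nearly complete tiling would be consistent with the high copy number of mitochondrial DNA, but only replicate 2 passed the 80% set for it. Whether copy number or another cause accounts for these regions cannot be told apart here, because the signal of the input samples was not analysed here, and no biological explanation was tested.

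The concentration of X among the strongest regions is the pattern most worth a second look. An excess of calls on X at every strength is argued against, since X held 17.4% of the weaker 50% of nuclear regions in replicate 1 and 17.02% in replicate 2, neither above the 17.7% of the span. These weak calls cannot speak for regions at a q value of 0.05 or less. There X was 1.26 times its share in replicate 1 and 1.07 times in replicate 2, with the strongest regions included. Extra copies of 1 stretch of X, as from a transgene array, are argued against by the spread of the 22 X regions among the 50 strongest over 13 of 18 bins of 1 Mb, and repeated calls of the same site by the distance of at least 44.6 kb between centres of the 17 X regions among the 25 strongest, a measure chosen with these positions known and in place of a merging test that could not have changed the share. This distance covers the 25 strongest only, since the combined list does repeat sites further down. Place 82 holds the same interval as place 4, X 6296317 to 6296792. Merging overlapping regions took the X regions of the whole combined list from 66 to 62. A single deviating replicate is argued against too, since the lower of the X shares of the 50 strongest regions was 38.0% (replicate 2, interval 25.9 to 51.8%). There were 0 immunoprecipitated samples from untagged worms, so binding by NHR-237 and recovery of other X-bound chromatin, such as the sites of the dosage compensation machinery that coats the hermaphrodite X, cannot be told apart, and positions of such sites were not used here.

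The replicate lists differed 2.58-fold in length (21504 against 8344 regions). At a q value of 0.05 or less the ratio was 1.30, which suggests that most of the difference in length lies in weak calls. Why replicate 2 had more weak calls, for example through depth or the number of background reads, was not tested, since the lists hold no reads.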

How the results depend on the processing

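Of 53 alternatives to 10 results, 42 kept the direction and the side of the threshold of 0.05, 1 fell exactly on the value expected without an effect (50.0% of autosomal regions in chromosome centres, no call), and 30 of the 53 were chosen after seeing the data. The sharing between the replicates stayed above random placement (permutation p = 0.0001) under all its alternatives and ranged from 30.0 to 55.0% of replicate 1 regions. The overlap of the combined list with the replicate lists, which rest on the same samples, ranged from 79.2 to 100% of combined regions in replicate 1 and from 63.4 to 99.4% in replicate 2, with the lowest values for replicate lists as long as the combined list, or, between the replicates, for a centre inside the other region. Alternatives to this overlap are counted above as kept, though with shared samples they could hardly fall to chance. Rank agreement fell to 0.0509 over scores of regions that overlap a combined region, where many scores tie, though ties were not tested as the cause. The X share of the combined list (20.5%, no call) passed the threshold in the better-ranked 50% of the list (24.8%, p = 0.0225), ranged from 19.3 to 22.05% with 1 replicate left out (p = 0.465 from replicate 2 alone and 0.0481 from replicate 1 alone, exact binomial test), and fell to 16.5%, below the span share, without the 25 strongest regions, so that it rests on those. The share in chromosome centres (47.8%, no call) crossed 50% without a call at 50.9% in the better-ranked 50% and at 50.3% with either replicate alone. Chromosome III (20.5%) ranged from 18.0 to 18.3% and chromosome IV (11.8%) from 12.4 to 16.1% with 1 replicate left out, both losing the call in replicate 2 alone, and chromosome IV lost it in the better-ranked 50% (11.2%, exact binomial test, adjusted p = 0.0559), which holds fewer regions; other causes were not tested. Chromosome V (12.1%) kept its call under its alternatives, from 12.4 to 14.3% with 1 replicate left out, and so did X among the 25 strongest, from 60.0 to 68.0% with 1 replicate left out. With more regions counted its share was lower, at 44.0% of the 50 strongest and 30.0% of the 100 strongest, both past the threshold. Both sets contain the same 25 regions, so they give no separate support, though they are counted above as kept. The added regions were on X for 20.0% at places 26 to 50 and 16.0% at places 51 to 100, near the span share. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no list analysed here. Planned tests of start sites, gene lists, motifs and the gene share of X were not run, for want of a WS220 annotation. The unknown read depth limits all statements on absent regions.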

Other observations

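The tests of spacing were written down before their values were seen. Combined regions occurred in local groups. After overlapping regions were merged into 311, there were 27 neighbouring pairs with centres 1 to 10 kb apart, against 9.20 ± 2.94 (SD) in 10000 random placements (permutation p = 0.0001, one-sided, the smallest possible). Regional density alone is argued against, since placing each region within 500 kb of its own position gave 9.67 ± 2.99 such pairs, with a 95th percentile of 15. There were 3 groups of 3 regions with neighbouring centres at most 10 kb apart, at I 1835287 to 1842431, III 8795511 to 8802355 and III 13060867 to 13070881. Gene-dense or open stretches shorter than 500 kb may give this spacing and were not tested, and no cause of the groups was tested beyond regional density.

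The strong X regions were also tested for even spacing. The 22 X regions among the 50 strongest had a median gap of 538 kb, from 44.6 to 1740 kb. The coefficient of variation of the gaps was 0.689, against 0.960 ± 0.183 (SD) for random positions on X, whose central 95% ran from 0.658 to 1.37 (permutation p = 0.0860, two-sided). The value lay within this range but near its lower edge, and with 21 gaps the question stays open.

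The highest score of the combined list would correspond to 244 tied regions by the relation that held in both replicate lists, whereas 230 regions carry it, a difference of 14. The replicate 1 list had 14 MtDNA regions at its highest score and the replicate 2 list had 18. Whether these regions have to do with the difference was not tested. The way in which the replicates were combined is not given.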
